A study of Mus musculus with 6 samples.

How the data were processed

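Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on γδ T cell precursors sorted from the thymus of C57BL/6 mice that lack the TCRβ gene and carry 1 Sox13 allele with a cyan fluorescent protein (CFP) knock-in. Per the labels' protocols, CD24-positive γδ thymocytes were split by CFP into a Sox13hi and a Sox13lo population, fixed with 1% formaldehyde and sonicated. The protocols give 1000000 cells for the SOX13 ChIP and 250000 cells for each histone ChIP, 17 cycles of amplification and library fragments of 300 to 500 bp. SOX13 was profiled in Sox13hi cells, and trimethylated histone H3 lysine 4 (H3K4me3) and lysine 27 (H3K27me3) in both populations. An input library of both populations is listed in the labels, and no file of it was used here.

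Each of the 5 ChIP libraries has 1 deposited peak list, with a position and a score for every peak, and no peak list pooled the populations. The score of a peak is the authors' own value. It is a positive number close to a multiple of 0.25, and its definition, the aligner, the peak caller, the thresholds and the control are not given in the sources used here. The build is mm9, per the submitters' processing notes. All peaks started on a 50 bp grid and ended 1 bp short of it, so widths were counted with the last base included. Starts are printed counting from 1 and ends as deposited. Read numbers were not analysed here, so the sequencing depth behind each list is unknown. A difference in depth or threshold between 2 libraries changes how many peaks are called. The score was therefore used only to rank or select peaks within a list, and scores were not compared between lists.

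Peak lists were compared by overlap of at least 1 bp. A peak was called shared if it overlapped any peak of the other population's list for the same mark, and otherwise it belonged to 1 population only. Because 1 peak can overlap several, the shared count depends on the list counted from. Shares carry 95% exact (Clopper-Pearson) binomial intervals, and differences of shares carry a Newcombe-type interval built from them. These intervals treat peaks as independent and cover counting error only. The overlap that chance gives was taken from 1000 random shifts. In each shift all peaks of a chromosome moved by 1 random distance and wrapped around the stretch between the first and last peak of any list. For shares of histone peaks carrying SOX13 by class, the SOX13 list was shifted, which keeps the widths of the histone peaks. Overlapping histone peaks of the 4 lists were also merged into regions, each described by the lists that covered it. A region with both marks holds a peak of each, which need not touch each other.

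There was 1 library per group. No difference between populations has a replicate check, and no p-value was computed. Alternatives fixed before the data were examined were an overlap of at least 50% of the shorter peak, the top 50% of each list by score, both lists of a mark limited to the same number of peaks by score, peaks within 1 kb merged, autosomes only, shifts of 50 kb to 1 Mb, and a 5 kb distance for peaks of 1 population. Where lists were cut by score, matching used the cut lists, so a peak whose only match was cut counts as unmatched. Leaving out sites called in all 5 lists, standardising widths in 5 bins, the merged regions, the shares of peaks on chromosome X and their differences, the 5 kb distance at equal list length and in the top 50%, and the overlap of both marks within a population were added after seeing the data.

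Promoter states, the gene lists, positions relative to genes and SOX and TCF motifs had also been planned. They need gene positions or sequence in mm9. The gene table at hand is on GRCm38, and coordinates were not converted between builds, so these analyses were not carried out and peaks are named by position. The rule fixed in advance names the 5 highest-scoring peaks of each mark and population with no peak of the other population within 5 kb, and the 5 highest-scoring SOX13 peaks. Peaks named in the closing section beyond these were chosen after their values were seen.

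Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures matplotlib 3.10.9. The overlap code was run on simulated data: 3 copies of the Sox13hi H3K27me3 list of 14842 peaks, in which a known share of peaks was kept in place, gave back that share with a largest difference of 0 percentage points. Moved peaks that met the original list were left out with the same code, so that outcome was fixed by the design. As a separate check, the counts of the overlap code equalled those of bedtools 2.31.1 for all 3 pairs of lists compared.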

Results

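SOX13, an HMG-box transcription factor, and 2 histone marks were mapped in γδ thymocytes with high (Sox13hi) or low (Sox13lo) activity of a Sox13 fluorescent reporter. H3K4me3 is a mark of active and poised promoters, and H3K27me3 is deposited by Polycomb repressive complex 2 at silenced genes. The series set out to relate where SOX13 sits on chromatin to these marks. Of the 6 libraries listed, 5 have a peak list used here, with 1 library per group and no replicates.

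The lists differed in length and in the shape of their peaks. SOX13 had 13807 peaks in Sox13hi cells, with a median width of 250 bp and 4.19 Mb covered in all. H3K4me3 peaks were the broadest, with a median of 800 bp in both populations. There were 20444 H3K4me3 peaks covering 17.7 Mb in Sox13hi and 18471 covering 16.4 Mb in Sox13lo, a ratio of 1.11 in number. H3K27me3 had 14842 peaks in Sox13hi, with a median width of 300 bp, against 7395 in Sox13lo, with a median of 350 bp. The Sox13hi H3K27me3 list was thus 2.01 times as long and covered 1.61 times as much sequence, 5.16 Mb against 3.21 Mb. Peaks over 2 kb numbered 679 and 646 in the H3K4me3 lists and 36 and 32 in the H3K27me3 lists, Sox13hi first.

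Peak density differed between chromosomes. Chromosome 11 was the densest autosome in each list, from 5.70 peaks per Mb for H3K27me3 in Sox13lo to 13.5 for H3K4me3 in Sox13hi. The sparsest autosome was chromosome 14 for SOX13 and H3K4me3 and chromosome 16 for H3K27me3. Chromosome X lay below every autosome in each list, with 0.915 SOX13 peaks per Mb. H3K4me3 had 431 X-linked peaks in Sox13hi and 423 in Sox13lo. H3K27me3 had 259 in Sox13hi, 1.75% of the list (95% exact binomial interval 1.54 to 1.97%), and 45 in Sox13lo, 0.609% (0.444 to 0.813%). With both H3K27me3 lists limited to the same length by score, 58 and 45 peaks were on chromosome X, which is 0.784% (0.596 to 1.01%) against 0.609%, a difference of 0.176 percentage points with an interval that includes 0 (-0.102 to 0.457). The X-linked H3K27me3 peaks in the top 50% of each list by score were 59 of 7421 (0.795%, 0.606 to 1.02%) and 14 of 3697 (0.379%, 0.207 to 0.635%), a difference of 0.416 points (0.0981 to 0.703). For H3K4me3 that setting gave 1.53% and 1.09%, a difference of 0.432 points (0.106 to 0.759), against -0.182 points (-0.479 to 0.113) as deposited. The Sox13hi excess in the top 50% was thus not particular to H3K27me3. In that setting the H3K27me3 lists again differ in length, and the Sox13lo share fell from 0.609% to 0.379% on cutting. The H3K27me3 difference there is therefore not free of list length.

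**Figure D1:**
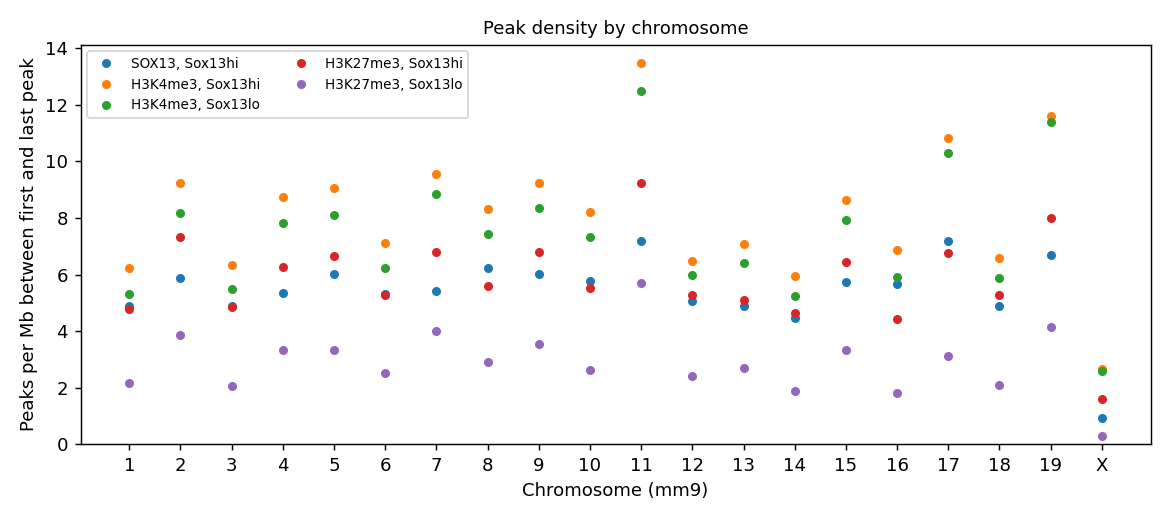
Peaks per Mb (vertical axis) on each autosome and chromosome X of mm9 (horizontal axis) for the 5 peak lists, 1 point per list and chromosome, with lengths taken between the first and last peak of any list. Chromosome 11 has the highest autosomal density in each list, and chromosome X the lowest density shown.

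The first comparison asked how far the active mark differed between the populations. Most H3K4me3 peaks were found in both: 14241 of the 20444 Sox13hi peaks (69.7%, 95% exact binomial interval 69.0 to 70.3%) overlapped a Sox13lo peak, and 14417 of the 18471 Sox13lo peaks (78.1%, 77.4 to 78.6%) overlapped a Sox13hi peak. Random shifts gave 1.34% ± 0.109 and 1.502% ± 0.164 (SD over 1000 shifts). The peaks found in 1 population only, 6203 in Sox13hi and 4054 in Sox13lo, were narrow, with median widths of 350 and 300 bp against 1000 and 950 bp for shared peaks. They were also concentrated among low scores. In the highest-scoring decile of the list, 99.9% of Sox13hi peaks and 100% of Sox13lo peaks were matched, against 7.0% and 14.7% in the lowest decile. With both lists at equal length, 76.4% and 77.4% were matched.

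High-scoring H3K4me3 peaks of 1 population were few. In Sox13hi, 4949 peaks (24.2%) had no Sox13lo peak within 5 kb. The highest-scoring of them was on chromosome 5, 104759851 to 104761099, with a score of 200.5, and it also held a SOX13 peak. The next were on chromosome 1, 24740751 to 24741299 (score 83.75), which held a SOX13 peak too, and, without SOX13, on chromosome 2, 104250001 to 104251099 (69.25), chromosome 9, 100999801 to 101000299 (65.0) and chromosome 3, 94180801 to 94182499 (62.75). In Sox13lo, 2936 peaks (15.9%) had no Sox13hi peak within 5 kb. The 2 shares were 18.2% and 16.7% at equal list length, and in the top 50% of each list 11.2% and 2.74%, Sox13hi first. Both settings cut lists before matching, so peaks whose only neighbour was cut are counted in these shares. Against the full list of the other population, at least 97.3% of Sox13hi and 99.1% of Sox13lo peaks in each decile from the sixth up overlapped a peak. The highest scores of the Sox13lo peaks without a neighbour were on chromosome 4, 62295901 to 62297649 (96.75), chromosome 7, 4817051 to 4818399 (75.25), and chromosome 3, 101090401 to 101091749 (69.0) and 153729101 to 153730049 (67.5), followed by chromosome 11, 74385251 to 74386249 (67.25). Of these 5, the site at 153729101 on chromosome 3 overlapped a SOX13 peak mapped in Sox13hi cells. None of the 10 sites held an H3K27me3 peak in either population. The genes at these positions were not analysed here.

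The same comparison for the repressive mark gave a lower share of matched peaks. Of the 14842 Sox13hi H3K27me3 peaks, 3638 (24.5%, 23.8 to 25.2%) overlapped a Sox13lo peak, and 3634 of the 7395 Sox13lo peaks (49.1%, 48.0 to 50.3%) overlapped a Sox13hi peak. Random shifts gave 0.261% ± 0.0501 and 0.530% ± 0.107. Matching again followed the score: 88.2% of the highest-scoring decile of Sox13hi peaks and 96.1% of that of Sox13lo peaks were matched, against 2.9% and 15.3% in the lowest decile. The 11204 peaks found in Sox13hi only and the 3761 in Sox13lo only had a median width of 250 bp each, against 500 bp for shared peaks. With lists of equal length 43.0% of Sox13hi and 44.0% of Sox13lo peaks were matched. The H3K4me3 lists are longer and their peaks broader. Relative to random shifts the overlap of the lists as deposited was 93.7 and 92.8 times for H3K27me3 and 51.8 and 52.0 times for H3K4me3. These folds do not rank the marks, because a larger shifted share lowers the highest fold that can be reached.

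**Figure D2:**
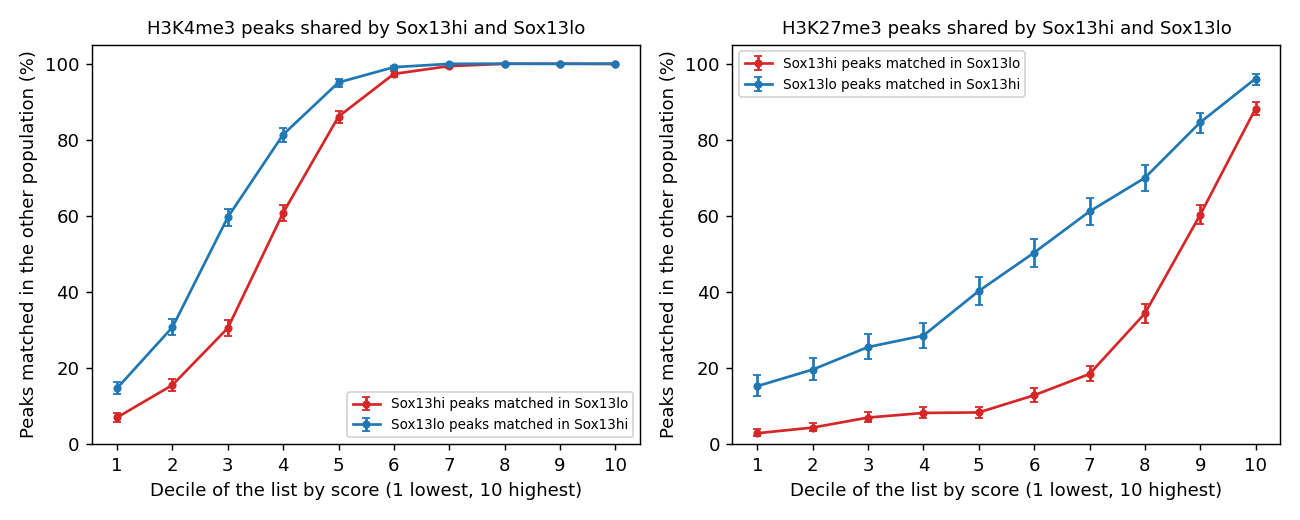
Percent of H3K4me3 (left) and H3K27me3 (right) peaks that overlap a peak of the other population (vertical axis), for each decile (10% of the peaks) of the list by score (horizontal axis). Points are shares with 95% exact binomial intervals, red for Sox13hi peaks and blue for Sox13lo peaks; in the highest decile H3K27me3 reaches 88.2% and 96.1% and H3K4me3 99.9% and 100%.

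In the lists as deposited, 8467 Sox13hi H3K27me3 peaks (57.0%) had no Sox13lo peak within 5 kb, against 1889 (25.5%) of the Sox13lo peaks. The difference in list length enters these shares. At equal list length the shares were 35.2% (34.1 to 36.3%) and 32.1% (31.0 to 33.2%), and in the top 50% of each list, where the lengths again differ, 45.3% and 13.4%. Here too, peaks whose only neighbour was cut from the other list are counted. The highest-scoring Sox13hi site was on chromosome 6, 40841651 to 40842249, with a score of 857. It held H3K4me3 in both populations and a SOX13 peak, so only the Sox13lo H3K27me3 list had no peak there. Enrichment at this site without an antibody was not examined. The next, on chromosome 2, 119063051 to 119063949 (score 142), and chromosome 10, 58275051 to 58276299 (138), held H3K4me3 in both populations and no SOX13 peak. The site on chromosome 14, 9119001 to 9119449 (127), held SOX13 but no H3K4me3, and that on chromosome 9, 77502701 to 77503649 (119.5), held both. The 5 highest-scoring Sox13lo sites were on chromosome 9, 58402201 to 58403499 (score 129), chromosome 8, 28195951 to 28197099 (116), chromosome 13, 36060301 to 36061399 (108.5), chromosome 6, 101326901 to 101327949 (103.5), and chromosome 9, 64989151 to 64989899 (99.0). All 5 held H3K4me3 in Sox13lo, and all but the chromosome 6 site held it in Sox13hi. The chromosome 8 site alone among them held SOX13.

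H3K27me3 peaks often lay on H3K4me3 peaks of the same population. This was so for 3277 Sox13hi peaks (22.1%, 21.4 to 22.8%) and 2853 Sox13lo peaks (38.6%, 37.5 to 39.7%), where random shifts gave 1.06% ± 0.0998 and 1.08% ± 0.150. At equal list length the shares were 38.1% and 38.6%, with overlapping intervals. They were 22.7% (21.8 to 23.7%) and 26.8% (25.4 to 28.3%) in the top 50% of each list by score, with separate intervals. That gap was narrower than as deposited, but the setting also cut the H3K4me3 lists. H3K27me3 peaks on the removed H3K4me3 peaks then counted as not overlapping, so the gap does not describe high-scoring H3K27me3 peaks in general. Against the full H3K4me3 lists the share was higher in Sox13lo in every decile by H3K27me3 score. Equal deciles are not equal ranks, because the highest decile holds 1485 peaks in Sox13hi and 740 in Sox13lo. Its 85.1% in Sox13hi lies between the 90.4% of the highest and the 68.6% of the ninth Sox13lo decile. This order by decile therefore does not show a difference beyond that in list length. The share rose with the H3K27me3 score, to 85.1% of the highest decile in Sox13hi and 90.4% in Sox13lo. Seen from the other side, H3K4me3 peaks of middle score held H3K27me3 most often. In Sox13hi 25.2% of the fifth decile did, against 4.5% of the lowest and 7.2% of the highest decile. In Sox13lo the maximum was 23.3%, in the fourth decile, against 8.0% of the lowest and 4.9% of the highest decile.

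**Figure D3:**
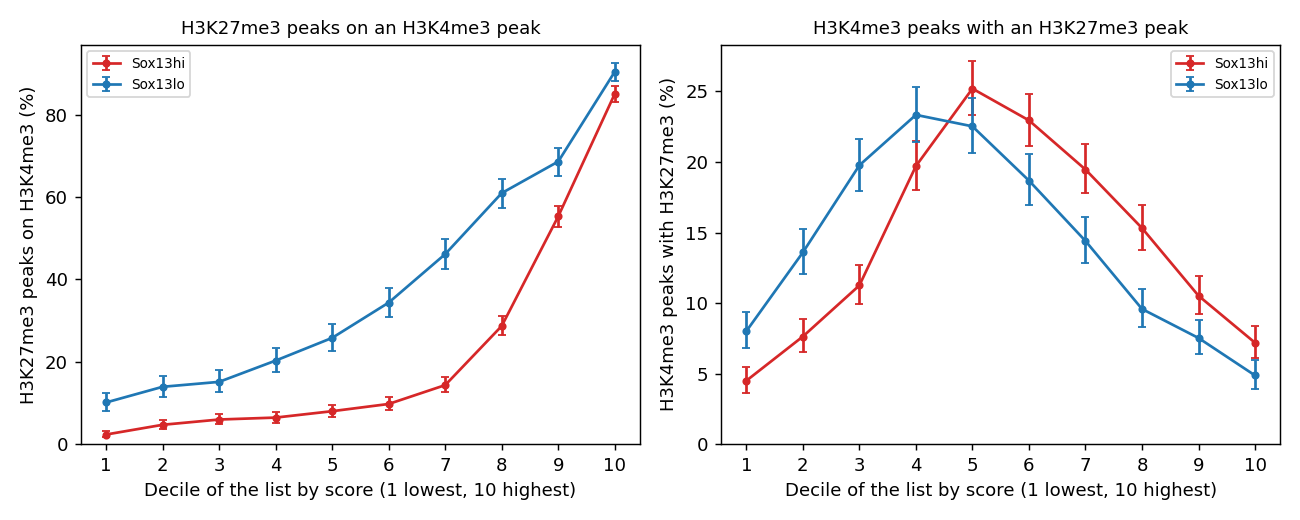
Left, percent of H3K27me3 peaks that overlap an H3K4me3 peak of the same population; right, percent of H3K4me3 peaks that overlap an H3K27me3 peak, each by decile of the list's own score (horizontal axis), with 95% exact binomial intervals. The left curves rise to 85.1% in Sox13hi (red) and 90.4% in Sox13lo (blue), and the right curves peak at middle scores, at 25.2% and 23.3%.

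Merging the 4 histone lists gave 37939 regions. H3K4me3 alone in both populations was the commonest state, with 11217 regions (29.6%), and H3K27me3 alone in both had 980 (2.58%), a number that was 630 with peaks within 1 kb merged and 1248 in the top 50% of each list by score. Both marks were present in 2914 regions in Sox13hi and 2587 in Sox13lo, and 1848 regions held both in each population. The order turned at equal list length, with 2539 regions in Sox13hi, 2586 in Sox13lo and 1740 in each. Among the top 50% of each list by score, where the lengths differ, 1423 regions in Sox13hi and 881 in Sox13lo held both, and 748 held both in each population. A change from 1 mark alone to the other was rare. H3K4me3 in Sox13hi with H3K27me3 in Sox13lo was seen in 170 regions and the opposite in 150. At equal list length the numbers were 171 and 92, and in the top 50% of each list 50 and 19. Regions with both marks in 1 population and H3K4me3 alone in the other numbered 581 for Sox13hi and 357 for Sox13lo.

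SOX13 peaks were then placed against the marks. In Sox13hi cells 1959 of the 13807 SOX13 peaks (14.2%, 13.6 to 14.8%) overlapped H3K4me3, 14.0 times the 1.01% ± 0.0996 of random shifts. H3K27me3 was overlapped by 511 (3.70%, 3.39 to 4.03%), 8.66 times the 0.427% ± 0.0696 of shifts. None of the 1000 shifts reached the observed share for any of the 4 histone lists. Against the Sox13lo lists, which are other cells than those in which SOX13 was mapped, the shares were 12.8% (12.3 to 13.4%) for H3K4me3 and 3.17% (2.89 to 3.48%) for H3K27me3. Without the sites called in all 5 lists, the shares on H3K27me3 were 1.72% in Sox13hi and 1.17% in Sox13lo, 4.48 and 5.51 times the shifts. Those sites were chosen for holding SOX13 and both marks. Leaving them out removes such overlaps by construction, so the lower shares and folds do not test the overlap. With all sites kept, the shares on H3K27me3 in the top 50% of each list by score were 4.29% and 3.71%, 15.4 and 22.3 times the shifts, against 8.66 and 12.5 times as deposited. The order of the populations turned at equal list length, with 2.998% (2.72 to 3.30%) in Sox13hi and 3.17% (2.89 to 3.48%) in Sox13lo.

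Most SOX13 peaks had neither mark. In Sox13hi 84.6% (83.9 to 85.2%) of them overlapped no histone peak, 11.7% overlapped H3K4me3 alone, 1.26% H3K27me3 alone and 2.44% both. The peaks with neither mark had a median score of 7.25, against 10.8 for those on H3K4me3 alone. The share on H3K4me3 rose from 4.7% in the lowest to 45.7% in the highest decile of SOX13 peaks by score, and that on H3K27me3 was 3.3% in the lowest and 7.9% in the highest. The 3 highest-scoring SOX13 peaks lay together on chromosome 17, 39979751 to 39985949, with scores of 6724, 805 and 793, and had no histone peak in any list. The first was 4100 bp wide, against a median of 250 bp for the list. As the input library was not used, enrichment there without an antibody was not examined, and these peaks cannot be taken as SOX13 binding. The fourth, on chromosome 6, 41071751 to 41072049 (score 523), overlapped a peak in all 4 histone lists. The fifth, on chromosome 6, 29698001 to 29699199 (471), overlapped H3K4me3 in both populations.

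**Figure D4:**
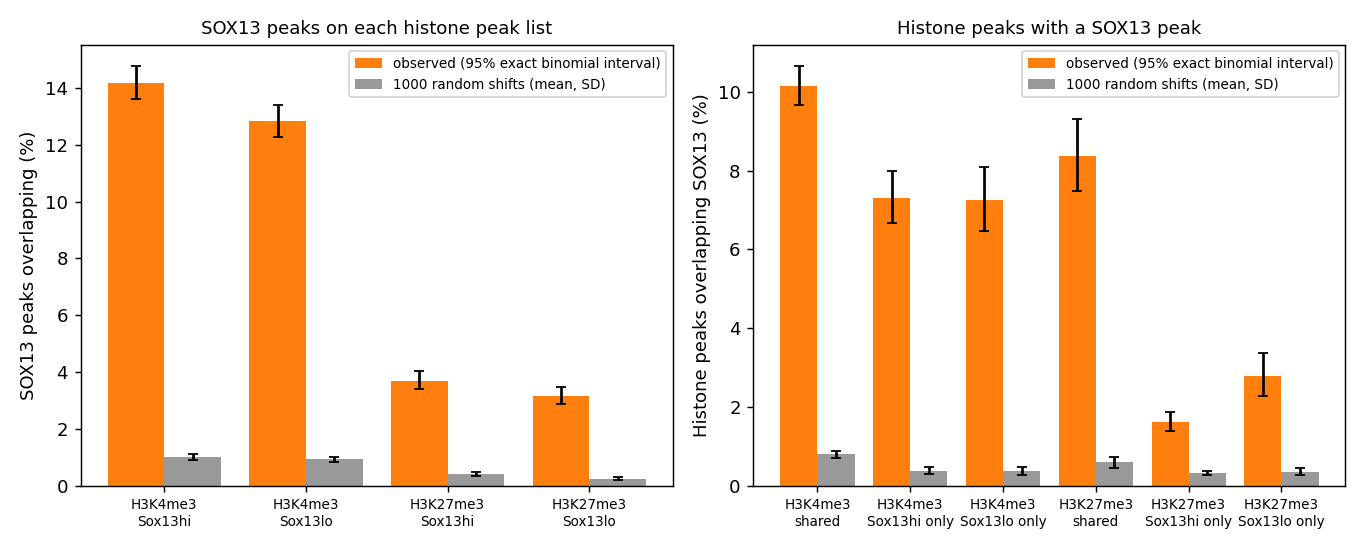
Left, percent of SOX13 peaks that overlap each histone list; right, percent of histone peaks that overlap a SOX13 peak, for peaks shared by both populations (counted from the Sox13hi list) or found in 1 only. Orange bars are observed shares with 95% exact binomial intervals, grey bars the mean and SD of 1000 random shifts; observed shares exceed the shifted ones throughout. In the lists as deposited, shared peaks hold SOX13 more often than peaks of 1 population. In the top 50% of each list the H3K4me3 shares are 8.08% (shared), 11.3% and 9.12% (1 population), with classes redefined after both lists were cut.

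The last comparison asked whether SOX13 peaks sat preferentially at marks that differ between the populations. Among H3K4me3 peaks, SOX13 was present at 10.2% (9.66 to 10.7%) of shared Sox13hi peaks, 7.30% (6.67 to 7.98%) of Sox13hi-only and 7.25% (6.47 to 8.09%) of Sox13lo-only peaks. Sox13hi-only and Sox13lo-only peaks thus differed by 0.0508 percentage points, with an interval from -1.004 to 1.083 that includes 0. Relative to random shifts the narrower peaks of 1 population held SOX13 18.9 and 19.0 times as often, and shared peaks 12.8 times. Shifted shares were 0.386% and 0.381% for the narrower peaks and 0.795% for the wider shared peaks. As width enters the shifted share, these folds do not rank the classes. With lists of equal length the difference was 1.37 points (0.165 to 2.57), higher in Sox13hi-only peaks. In the top 50% of each list by score, SOX13 was at 8.08% of shared, 11.3% of Sox13hi-only and 9.12% of Sox13lo-only peaks. There the classes were redefined after both lists were cut, so a peak whose match scored lower counts as 1 population only. In the full lists at least 97.3% of Sox13hi and 99.1% of Sox13lo peaks in each decile from the sixth up were matched. The order in that setting therefore does not describe peaks absent from the other population's list.

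For H3K27me3, SOX13 was present at 8.36% (7.48 to 9.30%) of shared Sox13hi peaks. It was present at 1.62% (1.40 to 1.88%) of Sox13hi-only and 2.79% (2.29 to 3.37%) of Sox13lo-only peaks, a difference of -1.17 points (-1.79 to -0.605). At equal list length the difference was -0.605 points (-1.34 to 0.127), and its interval included 0. It was -2.14 points (-3.11 to -1.29) for peaks with no peak of the other population within 5 kb, -1.67 (-2.93 to -0.619) in the top 50% of each list and -1.61 (-2.36 to -0.946) with peaks within 1 kb merged, all with intervals below 0. Each of these settings left the H3K27me3 lists unequal in length. In Sox13hi, SOX13 was at 0.943% of the lowest and 12.3% of the highest decile of H3K27me3 peaks by score. More low-scoring peaks in the longer list could thus lower the Sox13hi-only share. Removing sites called in all 5 lists left 1.87% of shared peaks with SOX13. That step removes shared peaks with SOX13 by construction wherever both H3K4me3 lists also have a peak, so it does not test the order of the classes.

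Among merged regions, SOX13 was found at 15.0% (13.4 to 16.7%) of those with both marks in both populations, with a median width of 1300 bp. All 277 of these regions with SOX13 are by definition at sites called in all 5 lists, for which enrichment without an antibody was not examined. It was found at 9.57% (9.03 to 10.1%) of those with H3K4me3 alone in both, with a median width of 1100 bp. Regions with H3K27me3 alone in both populations, 500 bp wide at the median, held SOX13 in 3.47% (2.41 to 4.81%). On autosomes alone the 3 shares were 13.1%, 9.77% and 2.90%, and in the top 50% of each list by score 14.0%, 7.47% and 5.69% (4.47 to 7.12%).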

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

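No paired analysis was possible because each group has 1 library, and for the same reason there was no replicate to leave out. Leaving out sites called in all 5 lists, the width standardisation, the merged regions, the shares of peaks on chromosome X and their differences, the 5 kb distance at equal list length and in the top 50%, and all values for H3K27me3 on H3K4me3 were chosen after seeing the data. The alternative settings for promoters, gene lists, gene positions and motifs were not run, as these analyses were not carried out. The fold over random shifts was not recomputed for the 50% overlap. Unknown depth limits how far any list can be called complete. Apart from the folds over shifts at the end, the values that follow lay outside the 95% interval of the value as deposited. The cause was not tested beyond what each setting removes.

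At an overlap of at least 50% of the shorter peak, 22.7% of Sox13hi and 45.6% of Sox13lo H3K27me3 peaks were shared, 13.6% and 3.32% of SOX13 peaks lay on Sox13hi H3K4me3 and H3K27me3, 20.2% (Sox13hi) and 36.2% (Sox13lo) of H3K27me3 peaks lay on H3K4me3, and 6.65% of Sox13hi-only H3K4me3 and 1.38% of Sox13hi-only H3K27me3 peaks held SOX13. In the top 50% of each list, sharing was 87.5% (Sox13hi) and 96.8% (Sox13lo) for H3K4me3 and 34.0% and 67.6% for H3K27me3. SOX13 peaks of that part lay on H3K4me3 in 13.1% (Sox13hi) and 11.2% (Sox13lo) and on H3K27me3 in 4.29% and 3.71%, and 26.8% of Sox13lo H3K27me3 peaks lay on H3K4me3. SOX13 was at 8.08% of shared, 11.3% of Sox13hi-only and 9.12% of Sox13lo-only H3K4me3 peaks, a Sox13hi-only excess of 2.16 points (-2.06 to 5.72), and at 3.51% of Sox13lo-only H3K27me3 peaks. All classes and overlaps of this setting were taken within the cut lists.

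With both lists of a mark at equal length, sharing was 76.4% (Sox13hi) and 77.4% (Sox13lo) for H3K4me3 and 43.0% and 44.0% for H3K27me3. SOX13 peaks lay on Sox13hi H3K4me3 in 13.6% and on Sox13hi H3K27me3 in 2.998%, below the 3.17% on Sox13lo H3K27me3, which did not change, and 38.1% of Sox13hi H3K27me3 peaks lay on H3K4me3. SOX13 was at 9.25% of Sox13hi-only H3K4me3 and 2.56% of Sox13hi-only H3K27me3 peaks, and Sox13hi-only minus Sox13lo-only was 1.37 points for H3K4me3 and -0.605 points for H3K27me3. This is the setting under which the interval for H3K4me3 no longer included 0 and that for H3K27me3 did. The H3K27me3 difference stayed below 0 under all 8 alternatives run on it, while that of H3K4me3 lay on both sides of 0. Among the 8, only equal list length removed the difference in the lengths of the H3K27me3 lists. The shared sign is therefore not a check against list length.

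Merging peaks within 1 kb gave 79.1% of Sox13lo H3K4me3 and 22.8% of Sox13hi H3K27me3 peaks shared, 2.86% of SOX13 peaks on Sox13lo H3K27me3, 21.4% (Sox13hi) and 41.5% (Sox13lo) of H3K27me3 peaks on H3K4me3, and SOX13 at 10.4% of shared H3K27me3 peaks. On autosomes, SOX13 peaks lay on H3K27me3 in 3.16% (Sox13hi) and 2.60% (Sox13lo), and 7.11% of shared H3K27me3 peaks held SOX13. With a 5 kb distance, SOX13 was at 8.11% of Sox13lo-only H3K4me3 and 3.60% of Sox13lo-only H3K27me3 peaks, and the H3K27me3 difference was -2.14 points. Without sites called in all 5 lists, 22.9% (Sox13hi) and 46.8% (Sox13lo) of H3K27me3 peaks were shared, SOX13 peaks lay on H3K4me3 in 12.3% and 10.9% and on H3K27me3 in 1.72% and 1.17%, H3K27me3 peaks lay on H3K4me3 in 20.3% and 35.9%, and SOX13 was at 8.32% of shared H3K4me3 and 1.87% of shared H3K27me3 peaks. That setting removes overlaps between the lists by construction, so its lower shares do not test them. Shifts of 50 kb to 1 Mb gave folds of 9.52 and 9.30 for SOX13 on H3K4me3, below the intervals of the folds as deposited, and 6.34 and 8.65 on H3K27me3, inside them, Sox13hi first. In the top 50% of each list the folds were 18.3 and 17.0 on H3K4me3 and 15.4 and 22.3 on H3K27me3, and only the 17.0 lay inside its interval as deposited.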

Other observations

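Sites called in every list formed a small set that scored high in the H3K27me3 and SOX13 lists, with median score percentiles of 90.6 (Sox13hi) and 80.1 (Sox13lo) for H3K27me3 and 76.2 for SOX13, against 58.3 and 48.7 for H3K4me3. Of 49268 merged sites, 275 had a peak in all 5 lists, and 30 of these were on chromosome Y. They made up 12.1% of the highest-scoring decile of H3K27me3 peaks in Sox13hi and 16.4% in Sox13lo, 6.01% of that of SOX13, and 1.76% and 1.57% of those of H3K4me3. The 3 highest-scoring H3K27me3 peaks of Sox13lo were all on chromosome Y, between 2857451 and 2893099, with scores of 1036, 842 and 557, and each overlapped a peak in the other 4 lists. Peak density on the mapped part of chromosome Y was 57.3 per Mb for SOX13 and between 28.6 and 34.9 per Mb for the histone lists. On chromosome 6, the highest-scoring H3K27me3 peak of Sox13hi, 41071601 to 41072199 with a score of 1843, was in all 5 lists. The input library, which would show whether these sites are enriched without an antibody, was not used here.

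SOX13 peaks far from either mark were common: 9362 of the 13807 (67.8%) had no histone peak of any list within 5 kb. Besides the 3 on chromosome 17, the highest-scoring were on chromosome 11, 108872751 to 108873399 (score 291.5), and chromosome 16, 57391401 to 57391949 (237). None of these sites was checked against the input library.

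Of the tests that follow, the ones on the unmatched H3K27me3 peaks were chosen after the result was seen. The others were set before their own results were seen, but after the overlaps they address. The first pattern was that 11204 of 14842 Sox13hi H3K27me3 peaks had no match in Sox13lo. A Sox13lo list that is merely a shorter subset of the Sox13hi list is argued against, since only 49.1% of Sox13lo peaks were matched in the longer list. Low-scoring calls that a second library would not call again remain a candidate explanation for part of it: 88.2% of the highest-scoring decile of Sox13hi peaks were matched, against 2.9% of the lowest. The matched share was 60.3% in the ninth, 34.4% in the eighth and 18.5% in the seventh decile. These shares break down the same unmatched total, and the Sox13lo list is shorter. They therefore do not show how much of the pattern such calls explain. The X-linked excess in Sox13hi went from 259 against 45 peaks to 58 against 45 at equal list length, where the interval of the difference in share includes 0 (-0.102 to 0.457 points). In the top 50% of each list it was 59 of 7421 against 14 of 3697, and the interval does not include 0 (0.0981 to 0.703 points). H3K4me3 had a similar difference in that setting, 0.432 points (0.106 to 0.759), so the excess there is not particular to H3K27me3. With 7421 against 3697 H3K27me3 peaks, the difference there is also not free of list length. A difference between the 2 populations stays open and untested, as does a difference in depth, because each population has 1 library.

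The second pattern was that high-scoring H3K27me3 peaks lay on H3K4me3 peaks. Carry-over from, or unspecific recovery of, the strongest H3K4me3 sites is argued against in both populations. The share of H3K4me3 peaks with H3K27me3 in the highest-scoring decile was 0.299 times that of the fifth and sixth deciles in Sox13hi and 0.237 times in Sox13lo. Sites called in all 5 lists are too few to account for it. They made up 12.1% of the highest-scoring decile of Sox13hi H3K27me3 peaks, of which 85.1% lay on H3K4me3. The 83.1% found without them was fixed by these counts and is not a separate test. Whether both marks sit on the same chromatin or in different cells of a sorted population cannot be read from peak lists, and no biological explanation was tested.

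The third pattern was the excess of SOX13 peaks on H3K4me3 over random shifts. Sites called in all 5 lists are too few to be the whole of it, as they held 317 SOX13 peaks, against 1959 on Sox13hi H3K4me3. Without them the observed share was 12.6 times the shifted one. With so few peaks removed that fold could not have fallen far, so it is not a separate test. Gene density at the scale of shifts of 50 kb to 1 Mb is also argued against, with 9.52 times the shifted share. Clustering at distances below 50 kb is not covered by these shifts and was not tested. Recovery that follows H3K4me3 strength, as unspecific recovery of open chromatin might give, cannot be told apart from SOX13 binding at active promoters. The share of H3K4me3 peaks with SOX13 in the highest decile was 1.67 times that of the fifth and sixth deciles in Sox13hi, between the bounds of 1.2 and 2 set in advance, and 2.08 times in Sox13lo. No SOX13 or control list from Sox13lo cells was compared.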
